A study of Mus musculus with 14 samples.

How the data were processed

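MicroRNA levels were measured with TaqMan rodent microRNA array cards, on which each well holds a real-time PCR assay for a known small RNA. There were 14 arrays in 2 tables of 7, a table of whole hearts and a table of lymphocytes. Per the labels, RNA of 3 animals (100 ng each, 300 ng in all) was pooled for each array. Per the labels it was isolated with a mirVana kit, reverse transcribed and preamplified with Megaplex primer pools, and run on a 7900HT instrument. Each card had 384 wells and 381 detectors, of which 375 were microRNA assays (335 with mouse names and 40 with rat names) and 6 were controls, MammU6 filling 4 wells.

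The values were exported by the authors from the SDS 2.4 software. Per the file headers and the values, the first column used holds the threshold cycle (Ct), in which a lower value is a higher level and 1 cycle is about 1 log2 unit. The deposited delta Ct is on an inverted log2 scale and equals the Ct minus that of snoRNA202 on the same card, with undetermined wells at 40, to within 5e-04 on each array. The deposited relative quantity is a ratio, 2 to the power of minus delta-delta Ct against the normal array of the same table, and 100% of the 1742 heart and 1464 lymphocyte values checked, those of at least 0.1, matched that formula within 1%. A column headed as the standard deviation of delta-delta Ct holds delta-delta Ct itself and was not used as an error. The baseline and threshold settings behind the Ct values were not given. In 1 well (let-7b, allogeneic heart pool 2) the deposited sample name differed from that of the other wells, and the well was left out.

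Levels were recomputed from the Ct values. Wells that were undetermined or at Ct 35 or later were set to 35, the detection limit. The level was minus the Ct after subtracting the mean Ct of the reference assays of that array, the microRNA assays detected on all 7 arrays of its table (210 for hearts and 137 for lymphocytes), so that a difference in level is a log2 fold change. An assay was tested in a comparison when it was detected on every array of at least 1 of the groups compared. The controls took no part in scaling or testing, and the plant control ath-miR159a was undetermined on 14 of 14 arrays. A fold change against a group detected on none of its arrays is a lower bound and is given as "at least". The values of such a group vary only with the array references. The SE and p of a bound therefore hold no variation of the microRNA within that group. In a group detected on some arrays, the others stood at the limit, and the number detected is given. Arrays give no counts, so the number of arrays limits the precision.

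Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 groups per table, two-sided), and an assay was called at a Benjamini-Hochberg adjusted p under 0.05 over the assays tested. The lone normal array of each table was assumed to vary like the other groups. The difference of the allogeneic effect between hearts and lymphocytes was an interaction contrast over the 12 transplant arrays, and the overlap of calls was set against a hypergeometric test. A total of 22 microRNA lists were tested in both allogeneic comparisons with limma's camera (preset correlation 0.01, and again with an estimated correlation) where at least 3 members were tested. Groups, comparisons, lists, the other settings to be tried and the rule for named assays were fixed before the data were examined. The rule took the 10 largest called rises and the 10 largest called falls with non-overlapping values in each allogeneic against syngeneic comparison. To these it added the 5 largest each way in each contrast with a normal array, up to 10 each way of the overlap, up to 4 members of each list with the smallest p, miR-182, and all endogenous controls. miR-182 was known from the study beforehand. Assays named below outside this rule were chosen after their values were seen.

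On simulated data with 40 changed assays in each of 20 simulations, a change of 1 log2 unit was called in 48.3% of cases at the noise of the heart table and in 25% at that of the lymphocyte table. A change of 2 was called in 83.5% and 66.3%, and 0.786% and 0.628% of unchanged assays were called. The interaction called 84% of differences of 3 and 1.30% of unchanged assays. Camera called 20 of 20 lists of 20 assays shifted by 1 and 5% of unshifted lists, at an unadjusted p under 0.05. The simulated assays varied independently. These shares therefore do not cover lists whose members vary together, such as the miR-17~92 list in the lymphocyte table (estimated correlation 0.75). The random seeds of the simulated interaction and of the random lists matched in level were changed once, after the results were seen, because they coincided with counts in the text. The values moved slightly and no statement changed with them.

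The other settings fixed beforehand began with scaling to MammU6, to snoRNA135 with snoRNA202, to the median of the reference assays or by quantiles. They also held detection limits of Ct 32 and 38, undetermined wells at 40, and no filter or detection on every array of both groups. The fit was varied by eBayes with trend and robust, the replicate number as a block, the arrays of 2 groups alone, a 2-fold change with an unadjusted p under 0.05, and each array left out in turn. Alternatives chosen after seeing the data were scaling to snoRNA202 with undetermined wells at 40 as the authors did (and, for the shares of calls higher and lower, to snoRNA202 with the limit of 35), the run day as a random or fixed block, a limit set after scaling, and leaving out wells that the software had marked. Gene positions came from a RefSeq gene table of the mouse assembly GRCm38.p6, joined to the assays by name, since the files name no assembly.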

Results

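MicroRNA levels were measured in mouse heart transplants, in whole grafts and in graft-infiltrating lymphocytes (GIL), the cells recovered from grafts. Syngeneic grafts were C57BL/6 hearts in C57BL/6 recipients. Allogeneic grafts, which the labels record as rejected, were BALB/c hearts in C57BL/6 recipients, so that the strain of the heart differs along with the group. There were 3 syngeneic and 3 allogeneic arrays of hearts taken on day 7, and 3 and 3 arrays of GIL taken on day 5. There was also 1 array of normal BALB/c hearts and 1 array of blood mononuclear cells (PBMC) of normal C57BL/6 mice. Each array held the RNA of 3 pooled animals, so that n counts pools. The heart arrays detected 228 to 260 of the microRNA assays, with a mean reference Ct of 22.4 to 23.9. The GIL and PBMC arrays detected 42.9 to 58.9% of them, at 23.2 to 28.0. Allogeneic GIL pool 3 stood apart with 161 assays detected (42.9%) and a reference Ct of 28.0. Of the small RNA controls, MammU6 differed between allogeneic and syngeneic hearts by 0.12 log2 units, U87 by 0.58, Y1 by -0.43, snoRNA135 by 0.30 and snoRNA202 by -0.15. In GIL the same differences were -0.82, 0.11, 0.33, -0.41 and -0.89. All 10 are relative to the microRNA reference and were not tested.

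The first comparison asked which microRNAs differ between rejected allogeneic hearts and syngeneic hearts on day 7. In allogeneic hearts all 3 members of the cluster of miR-183, miR-96 and miR-182 rose, each called under all 6 scalings, and 5 of 7 cardiac muscle microRNAs fell, of which 2 were called under all 6. Both assays of miR-142, which is made in blood cells, also rose, but neither was called when scaled to MammU6. miR-685 had the largest rise, 7.35 ± 0.49 log2 units (SE, n = 3 pools per group; 163-fold, limma adjusted p = 2.86e-04). miR-187 had the largest fall, being detected on 3 of 3 syngeneic and 0 of 3 allogeneic arrays. It was at least 283-fold lower (log2 fold change -8.15 ± 0.22, adjusted p = 1.27e-06). Of 238 assays tested, 41 were called higher and 36 lower, 70 of the 77 by more than 2-fold. In all, 113 had an unadjusted p under 0.05. The 3 allogeneic values lay apart from the 3 syngeneic values in 129 assays (54.2%), where chance gives 10%.

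After miR-685, the largest rises were those of miR-451, an erythroid microRNA (3.99 ± 0.71, 15.9-fold), miR-147, which is induced in macrophages (3.69 ± 0.44, 12.9-fold), miR-96 (3.40 ± 0.27, 10.5-fold) and miR-153 (3.10 ± 0.60, at least 8.57-fold, detected on 0 of 3 syngeneic arrays). These were followed by miR-182 (2.64 ± 0.40, 6.25-fold), miR-467c (2.59 ± 0.23, 6.02-fold), miR-210, which hypoxia induces (2.55 ± 0.31, 5.88-fold), miR-183 (2.45 ± 0.48, 5.47-fold) and miR-342-5p (2.36 ± 0.41, 5.15-fold). Their limma adjusted p ran from 6.29e-04 to 0.0118. After miR-187, the largest falls were those of miR-367 (log2 fold change -3.40 ± 0.53, detected on 2 of 3 allogeneic arrays), miR-135a (-3.06 ± 0.27), miR-135b (-2.74 ± 0.54) and miR-302b (-2.32 ± 0.36, at least 4.98-fold lower, detected on 0 of 3 allogeneic arrays). Below them came miR-208b, which lies in a cardiac myosin gene (-2.29 ± 0.34), miR-676 (-2.11 ± 0.29), miR-199a-3p (-1.94 ± 0.29), miR-204 (-1.92 ± 0.28) and miR-455 (-1.86 ± 0.39). Their adjusted p ran from 7.05e-04 to 0.0144. In the mouse assembly GRCm38.p6, Mir182, Mir96 and Mir183 lie on chromosome 6 at 30165918 to 30165992, 30169446 to 30169551 and 30169668 to 30169737. Mir187 lies on chromosome 18 at 24429110 to 24429170. The relative quantity of miR-182 deposited by the authors, with normal hearts at 1, was 67.8 to 115 in allogeneic and 9.12 to 14.8 in syngeneic hearts.

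**Figure D1:**
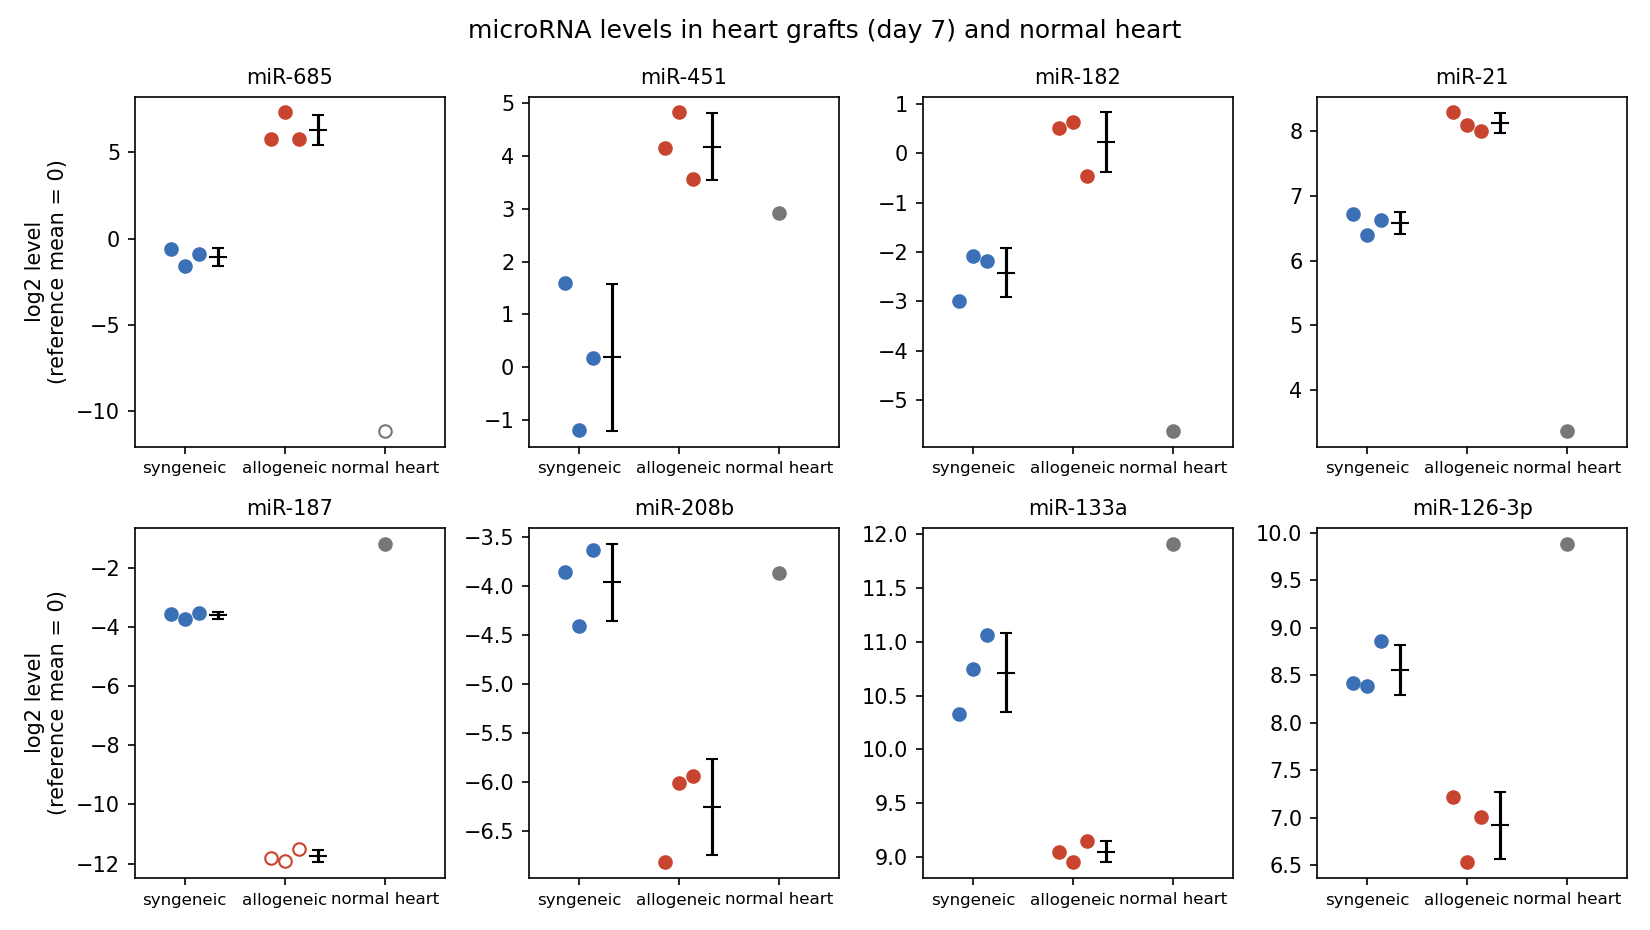
Level of selected microRNAs (log2, minus the Ct relative to the reference assays, each panel on its own axis) in normal, syngeneic and allogeneic hearts; points are arrays (n = 1, 3 and 3 pools), open circles stand at the detection limit, and black bars are the mean ± SD. miR-685 was 7.35 log2 units higher in allogeneic than in syngeneic hearts, and miR-187 was detected on 3 of 3 syngeneic and 0 of 3 allogeneic arrays.

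Of the lists for muscle and leukocytes, the cardiac muscle list went down in allogeneic hearts (median -1.67 log2 units, 5 of 7 members lower, 6 adjusted over the list alone; camera adjusted p = 0.0107, adjusted p = 0.408 with an estimated correlation). miR-208b (-2.29), miR-133b (-1.79), miR-133a (-1.67), miR-1 (-1.53) and miR-208 (-1.48) fell. miR-490 (-4.12 ± 2.47, adjusted p = 0.234) and miR-499 (-0.74, 0.0587) did not pass. The activated T cell list went up (median 0.94, 4 of 10 higher and 1 lower, 6 and 1 adjusted over the list alone; adjusted p = 0.0321, adjusted p = 0.408 with an estimated correlation). Its members miR-96, miR-182, miR-183 and miR-21 (1.55 ± 0.21) rose. miR-182 was known from the study when the lists were fixed. The tests of this list and of the miR-183 cluster list are therefore not independent of that knowledge. miR-214, which fibroblasts also make, fell (-1.85 ± 0.48), and miR-155 stood at 1.10 ± 0.35 (adjusted p = 0.0524). Both pan-leukocyte assays rose, miR-142-3p by 1.64 ± 0.25 and miR-142-5p by 1.02 ± 0.30 (2 adjusted over the list alone; too few for the list test). In the resting lymphocyte list, miR-342-5p (2.36) and miR-342-3p (1.30) rose and miR-26a (-0.80) fell among 7 members (2 and 1 adjusted over the list alone). The median was -0.35, the mean 0.17 and the test pointed down (adjusted p = 0.736), with miR-150 at -0.49. None of the 4 myeloid members passed over all assays or adjusted over the list alone (miR-223 0.96, miR-125a-3p 0.67, miR-125a-5p -0.28, miR-511 -3.89 ± 2.37). Their median was 0.20, which is negative when scaled to the median, their mean was -0.64 and the test pointed up (adjusted p = 0.77).

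The list of the miR-183 cluster, whose 3 members the activated T cell list also holds, went up (median 2.64, 3 of 3 higher, 3 adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.408 with an estimated correlation). The list of miR-17~92 and its paralogues, which proliferating lymphocytes make, went up (median 0.63, 3 of 11 higher, 3 adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.531 with an estimated correlation). Its called members were miR-106b (1.41), miR-18a (1.28) and miR-25 (1.26). The miR-30 family, abundant in heart muscle, went down (median -0.80, 3 of 5 lower, 5 adjusted over the list alone; adjusted p = 0.0321, adjusted p = 0.531 with an estimated correlation). Its called members were miR-30c (-1.25), miR-30e (-1.02) and miR-30b (-0.80). miR-222 (1.22) and miR-221 (1.15) rose (2 of 2, 2 adjusted over the list alone), as did miR-210, the sole hypoxia member (1 adjusted over the list alone).

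No other list passed in hearts. In the erythroid and platelet list (median 0.80, adjusted p = 0.341), miR-451 and miR-15b (1.18) rose and miR-16 (0.43) and miR-486 (-0.16) did not pass. In the endothelial list (median -1.05, adjusted p = 0.378), miR-126-3p (-1.64 ± 0.27) and miR-126-5p (-1.30 ± 0.20) fell, miR-10a (1.00) rose and miR-10b (-0.80) did not pass. Of the smooth muscle assays (median -0.75), miR-145 fell (-1.03) and miR-143 (-0.47) did not pass. In the fibroblast list (median -0.44, adjusted p = 0.634), miR-199a-3p (-1.94) and miR-214 (-1.85) fell, miR-21 rose and miR-29c stood at -0.66. In the NF-kB list 1 of 6 members was lower, miR-187, and its median of 0.15 differed in sign from its mean of -1.11 and from the test (adjusted p = 0.736). In the miR-15/16 family (median -0.33, adjusted p = 0.634) miR-497 (-1.72), miR-322 (-1.12) and miR-195 (-0.98) fell and miR-15b rose. In the epithelial list (median 1.08, adjusted p = 0.378) miR-200a (1.63), miR-141 (2.83-fold) and miR-200c (1.08) rose and miR-203 stood at -0.88. Of the p53 and miR-34 list (median -0.22, 0.633), miR-34b-3p fell by 1.00. Of the Dlk1-Dio3 imprinted cluster (25 assays, median -0.18, 0.634), miR-136 (-1.59) and miR-434-3p (-1.01) fell. No member was called in the let-7 family (8 assays, median -0.04, 0.634), the miR-23/27/24 clusters (4 assays, -0.13, 0.736, miR-23b -0.64) or the other-organ list (miR-137, 0.14). The medians of the NF-kB, miR-23/27/24, let-7 and other-organ lists change sign under some of the other scalings.

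The counts of these lists adjusted over the list alone, higher and lower, were 2 and 0 for the erythroid, 1 and 2 for the endothelial, 0 and 1 for the smooth muscle, 1 and 2 for the fibroblast, and 2 and 1 for the NF-kB lists. They were 1 and 3 for the miR-15/16, 3 and 1 for the epithelial, 0 and 1 for the p53 and miR-34, 0 and 2 for the Dlk1-Dio3, and 0 and 0 for the let-7, miR-23/27/24 and other-organ lists.

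The heart counts varied with run day, arrays and scaling. Within the 2 run days that held both groups, miR-685 differed by 6.42 and 7.40 log2 units and miR-187 by -8.26 and -7.79. With run day as a fixed block, miR-685 and miR-187 were the 2 calls left, because 1 residual degree of freedom remained in place of 4. Over the 77 calls the median size was 1.59 log2 units (median SE 0.29) without the block and 1.44 (0.26) with it, and 69 had an unadjusted p under 0.05. The calls had been chosen on the same arrays. Run day as a random block (consensus correlation -0.03) left 77. The replicate block left 46, and without syngeneic pool 2, syngeneic pool 3 or allogeneic pool 1 there were 42, 45 and 43. The 41 to 36 split was 42 to 23 when scaled to snoRNA202 (which moved the median of all assays by 0.15) and 24 to 56 when scaled to the median of the reference assays (a shift of -0.26). Scaling to MammU6 left 34 calls (a shift of -0.12), and 18 rises and 12 falls were called under all 6 scalings. In hearts 0 calls turned, though miR-133a stood at 0 by quantiles. The calls of miR-342-3p (held under 9 of 24 alternatives), miR-10a, miR-142-5p, miR-200a and miR-26a (10 of 24 each) were lost under most alternatives.

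The second comparison asked which microRNAs differ between GIL preparations from allogeneic and syngeneic grafts on day 5. MicroRNAs linked to leukocytes (miR-142-3p, 1.60), fibroblasts (miR-214, -3.45) and muscle (miR-133a, 1.67) were themselves called. The arrays therefore cannot tell a change within lymphocytes from a change in the mix of cells recovered. In allogeneic GIL 18 of 24 microRNAs of the Dlk1-Dio3 imprinted cluster were called lower relative to the microRNA reference, of which 2 were called under all 6 scalings. Of the miR-17~92 clusters 7 of 11 were called higher. Of the activated T cell list 3 of 9 were called higher, miR-182, miR-155 and miR-146a, and 3 lower. miR-211 had the largest rise, being detected on 3 of 3 allogeneic and 0 of 3 syngeneic arrays. It was at least 275-fold higher (log2 fold change 8.10 ± 0.44, n = 3 pools per group, limma adjusted p = 2.27e-04), though the software had marked 3 of the 4 GIL and PBMC wells with a Ct for it. miR-182 rose by 2.95 ± 0.42 log2 units (7.73-fold, adjusted p = 0.00713). Of 201 assays tested, 25 were called higher and 48 lower, 66 of the 73 by more than 2-fold. In GIL, 102 had an unadjusted p under 0.05. The 3 allogeneic values lay apart from the 3 syngeneic values in 116 assays (57.7%), where chance gives 10%.

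The other large rises were those of miR-669a (6.41 ± 1.79, detected on 1 of 3 syngeneic arrays), miR-547 (2.70 ± 0.45), miR-18a (2.28 ± 0.33), miR-7b (2.23 ± 0.20), miR-467a (2.19 ± 0.33), miR-7a (2.16 ± 0.31), miR-130b (2.12 ± 0.31) and miR-685 (2.12 ± 0.26). Their limma adjusted p ran from 0.0026 to 0.0404. The largest falls were those of miR-741 (log2 fold change -12.76 ± 1.83, detected on 1 of 3 allogeneic arrays, with 4 of 4 wells marked by the software), miR-370 (-6.56 ± 1.06, at least 94.5-fold lower) and miR-382 (-6.46 ± 1.30, 1 of 3 allogeneic arrays). Next came miR-672 (-5.61 ± 1.01, at least 48.7-fold lower), miR-409-3p (-5.24 ± 0.92, 2 of 3), miR-503 (-4.48 ± 0.98, at least 22.3-fold lower) and the rat-named assay miR-351 (-4.39 ± 0.22, 20.9-fold lower). The last were miR-125b-3p (-4.22 ± 1.01, at least 18.7-fold lower), miR-455 (-3.98 ± 0.92, 2 of 3) and miR-134 (-3.90 ± 1.17, 2 of 3). Their adjusted p ran from 2.27e-04 to 0.0478. miR-370, miR-672, miR-503 and miR-125b-3p were detected on 0 of 3 allogeneic arrays. The relative quantity of miR-182 deposited by the authors, with PBMC at 1, was 113 to 142.6 in allogeneic and 6.17 to 13.2 in syngeneic GIL.

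The Dlk1-Dio3 imprinted cluster, whose microRNA genes are expressed from the maternal chromosome, went down in GIL (median -2.73 log2 units, 18 of 24 lower, 20 adjusted over the list alone; camera adjusted p = 5.53e-06, adjusted p = 0.517 with an estimated correlation). miR-410 (-2.34 ± 0.26), miR-376a (-2.76 ± 0.32), miR-495 (-2.56 ± 0.41) and miR-127 (-2.69 ± 0.43) fell, and miR-323-3p was at least 12.4-fold lower. miR-376b stood at 1.32 ± 0.95 and miR-667 at -5.41 ± 6.24 without passing. Mir379 and Mir410 lie on chromosome 12 at 109709060 to 109709125 and 109743715 to 109743795. The list median stayed below 0 under the 5 other scalings, and all 18 calls kept their direction, but most calls were lost when scaled to small RNA controls. There were 9 falls called when scaled to MammU6 (median -1.92), 2 to snoRNA135 with snoRNA202 (-2.08), 2 to snoRNA202 (-1.84), 17 to the median (-2.52) and 14 by quantiles (-2.23). miR-382 and miR-409-3p were called under all 6. In PBMC, 17 of the 24 assays were undetected. Beside this list, the 3 fibroblast-linked miR-199a and miR-214 assays had a median of -1.38 (miR-214 -3.45), and the cardiac muscle assays had a median of 1.66.

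**Figure D2:**
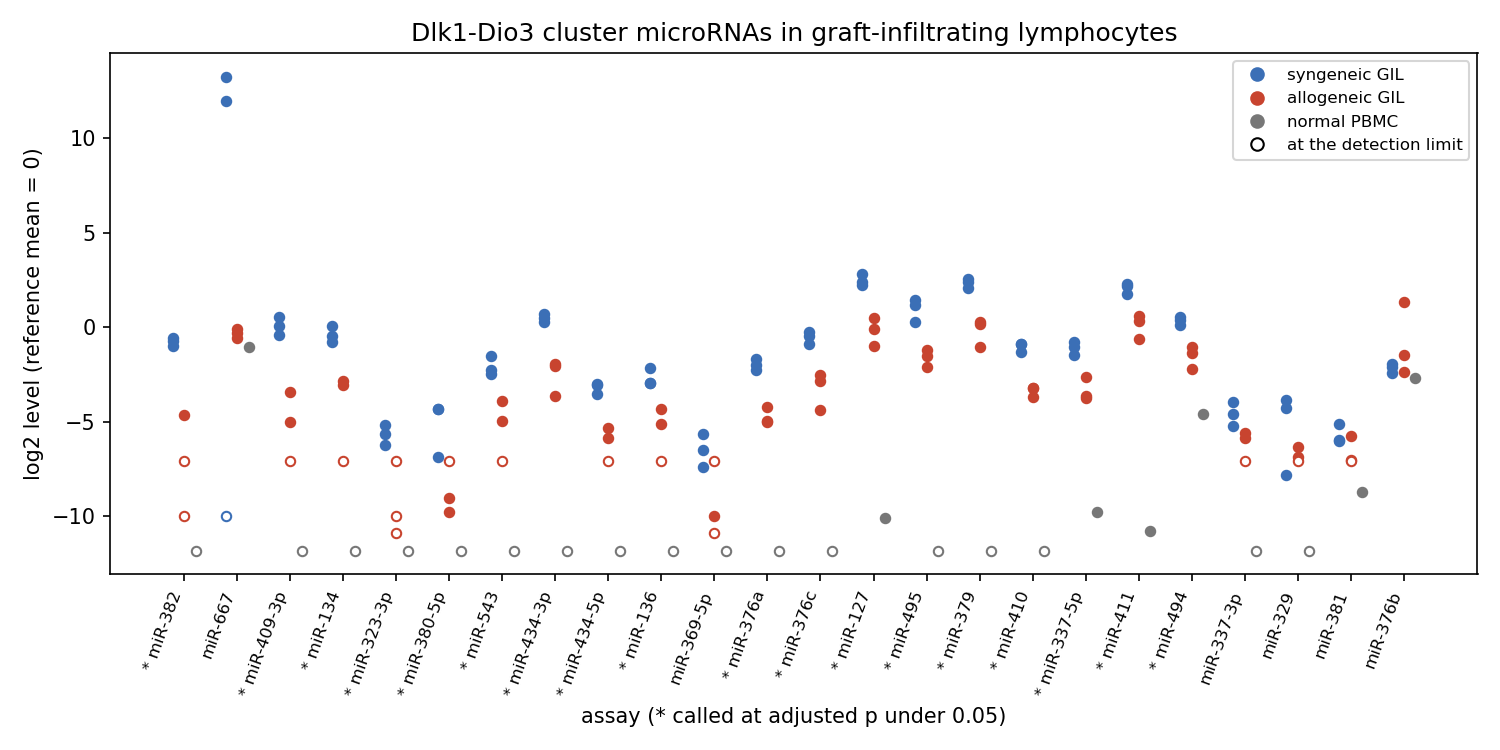
Level of the 24 tested Dlk1-Dio3 microRNAs (log2, minus the Ct relative to the reference assays) in syngeneic GIL, allogeneic GIL and normal PBMC. Points are arrays (n = 3, 3 and 1 pools), and open circles stand at the detection limit. Stars mark the 18 called between allogeneic and syngeneic GIL at a limma adjusted p under 0.05. The median log2 fold change of the list was -2.73, and miR-376b stood at 1.32 without passing.

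The list of miR-17~92 and its paralogues went up in GIL (median 0.93, 7 of 11 higher, 7 adjusted over the list alone; adjusted p = 3.87e-04, adjusted p = 0.517 with an estimated correlation). miR-18a (2.28), miR-20b (1.44), miR-106b (0.99) and miR-25 (0.98) were among the calls. The activated T cell list went both ways (median 0.62, 3 of 9 higher and 3 lower, 5 and 3 adjusted over the list alone; adjusted p = 0.427). miR-182, miR-155 (1.98 ± 0.26) and miR-146a (1.16 ± 0.24) rose, and miR-214 (-3.45 ± 0.46), miR-31 (-2.03 ± 0.35) and miR-132 (-1.25 ± 0.33) fell. In the fibroblast list miR-29c rose (1.46) and miR-214, miR-199a-3p (-1.38) and miR-199a-5p (-1.31) fell among 7 members (1 and 3 adjusted over the list alone). Its median of 0.09 and its test, which pointed up (adjusted p = 0.928), differed in sign from its mean of -0.49. In the cardiac muscle list miR-133a (1.67 ± 0.40) and miR-133b (1.54 ± 0.47) rose and miR-1 stood at 1.66 ± 0.61 (3 of 3 adjusted over the list alone, adjusted p = 0.151). miR-142-3p rose (1.60 ± 0.34) and miR-142-5p stood at 1.00 (2 of 2 pan-leukocyte assays adjusted over the list alone). In the cluster of miR-182, miR-183 stood at 0.66 (median 1.81, 2 of 2 adjusted over the list alone).

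None of the remaining lists passed in GIL. miR-125a-5p of the myeloid list fell (-1.87 ± 0.30; 3 assays, median -0.95, adjusted p = 0.359), beside miR-223 at -0.83 and miR-125a-3p at -0.95. miR-126-3p of the endothelial list fell (-1.07; 3 assays, median -0.24, 0.831), beside miR-126-5p at -0.24 and miR-10a at 0.15. In the NF-kB list miR-155 and miR-146a rose and miR-132 fell among 5 members, and its median of -0.08 differed in sign from its mean of 0.30 and from the test (0.459). miR-34b-3p fell (-2.26; p53 and miR-34 list, 5 assays, median -2.26, 0.459), as did miR-497 (-1.30; miR-15/16 family, 6 assays, median 0.06, mean -0.21, test up, 0.928). miR-27b (0.78; miR-23/27/24 clusters, 4 assays, median 0.23, 0.459) and miR-124, a neuronal microRNA of the other-organ list (1.80), rose. No member was called in the resting lymphocyte list (6 assays, median 0.54, 0.268, miR-181a 0.62), the erythroid list (3 assays, 0.67, 0.359, miR-451 0.67), the miR-30 family (5 assays, 0.57, 0.268, miR-30e 0.63) or the let-7 family (8 assays, -0.52, 0.831, let-7c -0.95). Nor was any called among the epithelial list (3 assays, 0.85, 0.284, miR-141 2.90 ± 1.07), miR-221 (-0.28) and miR-222 (0.09; median -0.10), smooth muscle (miR-143 0.56, miR-145 -0.15, median 0.20) or hypoxia (miR-210, 0.16). The medians of the endothelial, NF-kB, let-7 and miR-221 lists are positive under some of the other scalings. The counts adjusted over the list alone, higher and lower, were 0 and 1 for the myeloid and the miR-15/16 lists, 2 and 1 for the NF-kB, 0 and 2 for the p53 and miR-34, 3 and 0 for the miR-30, and 1 and 0 for the other-organ list. They were 0 and 0 for the endothelial, miR-23/27/24, resting lymphocyte, erythroid, let-7, epithelial, miR-221, smooth muscle and hypoxia lists.

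Scaling and arrays limited the GIL counts. The 25 to 48 split was 34 to 20 when scaled to MammU6, 21 to 10 to snoRNA135 with snoRNA202, 38 to 10 to snoRNA202, 36 to 39 to the median and 34 to 31 by quantiles. These scalings moved the median of all assays (-0.24) by 0.82, 0.65, 0.89, 0.22 and 0.30, so that rises and falls are relative to the microRNA reference. In GIL 0 calls turned, and 19 rises and 9 falls were called under all 6. No run day held both groups, so that run day and group cannot be told apart. There were 46, 40 and 40 calls without syngeneic pool 1, 2 or 3. The calls of miR-126-3p (held under 7 of 23 alternatives), miR-134 (9 of 22), miR-27b (10 of 23) and miR-132 (11 of 23) were lost under most alternatives.

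The third comparison asked whether the allogeneic effect differed between hearts on day 7 and GIL on day 5, over the 198 assays tested in both. Both tissues shared rises of miR-182, the Sfmbt2 cluster members miR-669a, miR-467a and miR-467c, miR-7a and miR-7b, and falls of miR-214, miR-224 and miR-455. The Sfmbt2 cluster was not tested as a set. Of the other miR-467 assays, miR-467b (1.90 in hearts, -0.82 in GIL) and miR-467e (1.92 and 3.68) were called in hearts alone. A hypergeometric test of the overlap takes assays as independent draws. Neighbouring microRNA genes changed alike (permutation p = 1e-04 over all clusters in each tissue). The shared rises hold such neighbours, among them miR-106b with miR-25. The hypergeometric p-values for rises and falls can therefore be too small, and no test by cluster was run. In all, 12 assays were called higher in both (35 in hearts and 23 in GIL, 4.07 for independent lists, exact hypergeometric test, p = 5.35e-05). Another 12 were called lower in both (29 and 47, 6.88 for independent lists, exact hypergeometric test, p = 0.0177). Of these, miR-685 rose by 7.35 log2 units in hearts and 2.12 in GIL, miR-182 by 2.64 and 2.95, miR-7b by 2.11 and 2.23, miR-7a by 1.98 and 2.16, miR-130b by 1.47 and 2.12 and miR-18a by 1.28 and 2.28. The shared falls had log2 fold changes of -1.86 and -3.98 for miR-455, -1.85 and -3.45 for miR-214, and -1.75 and -2.78 for miR-224. They were -1.59 and -2.82 for miR-136, -1.72 and -1.30 for miR-497 and -1.64 and -1.07 for miR-126-3p. The other assays called in both were miR-142-3p, miR-106b and miR-25 (higher) and miR-434-3p, miR-199a-3p, miR-34b-3p, miR-193b, miR-574-3p and miR-542-5p (lower).

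The muscle microRNAs went opposite ways, miR-133a with -1.67 in hearts and 1.67 in GIL (difference adjusted p = 0.00204) and miR-133b with -1.79 and 1.54 (0.00914). They were the 2 assays called in opposite directions. By quantiles miR-133a stood at 0 in hearts, and the GIL calls held under 17 of 23 (miR-133a) and 12 of 23 alternatives (miR-133b). The interaction called 57 of the 198 assays, 41 with a higher effect in hearts and 16 with a lower effect. These directions depend on scaling. The counts were 6 and 9 when scaled to MammU6, 8 and 19 to snoRNA135 with snoRNA202, 9 and 20 to snoRNA202 with undetermined wells at 40, 25 and 33 to the median and 23 and 26 by quantiles. The effect of miR-685 was higher in hearts by 5.23 ± 0.59 log2 units (adjusted p = 7.44e-04), that of miR-210 by 2.398 ± 0.46 and that of miR-451 by 3.32 ± 0.86. The day differed along with the tissue. In hearts the strain of the heart also differed with the group, and in GIL no run day held both groups. The interaction cannot separate these from a difference between tissues. Scaling to MammU6 left 15 calls of the interaction and 9 shared calls, to snoRNA135 with snoRNA202 27 and 12, and the replicate block left 31 and 11.

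**Figure D3:**
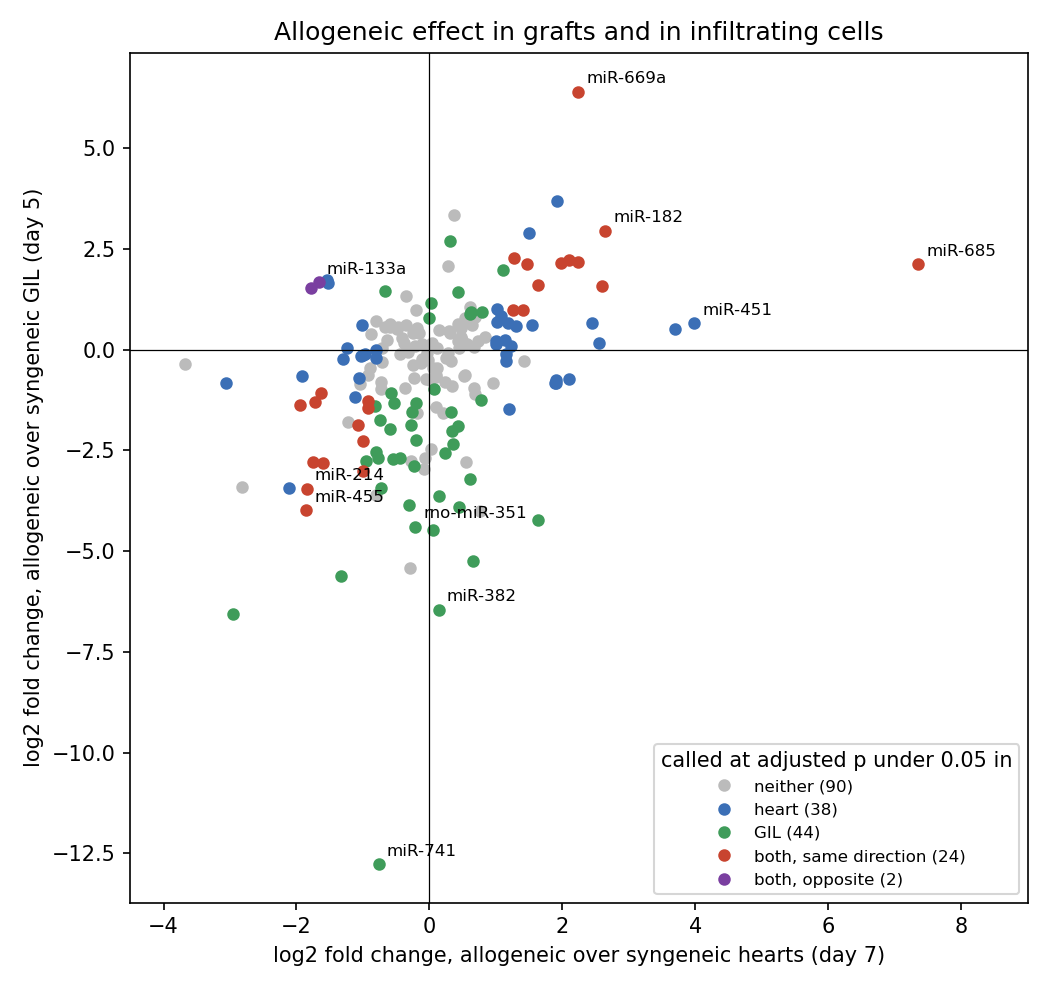
Log2 fold change between allogeneic and syngeneic samples in hearts (x axis, day 7) against GIL (y axis, day 5) for the 198 assays tested in both, each point being an assay (n = 3 pools per group and tissue) coloured by where it was called at an adjusted p under 0.05. The 24 assays called the same way lie in the upper right and lower left, and miR-133a and miR-133b lie in the upper left.

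The last contrasts set the grafts and GIL beside the lone normal array of each table. That array was assumed to vary like the other groups, on which all SE, adjusted p and counts here rest. It also had a run day with no other array of its table, so that run day and group cannot be told apart. Against normal BALB/c hearts, allogeneic hearts had 63 assays higher and 62 lower of 241. C57BL/6 syngeneic hearts, which also differ in strain, had 28 and 18 of 242. miR-21, which rises in stressed hearts, was 27.1-fold higher in allogeneic (log2 fold change 4.76 ± 0.30, n = 3 and 1 pools, limma adjusted p = 4.79e-05) and 9.25-fold higher in syngeneic hearts (3.21 ± 0.30). miR-1, the main muscle microRNA, was lower in both (-3.09 ± 0.41 and -1.56 ± 0.41). Undetected in normal hearts were miR-685 (at least 17.44 log2 units higher in allogeneic and 10.09 in syngeneic hearts), miR-669a (12.83 and 10.59), the rat-named miR-532-5p (12.21 and 11.32) and miR-467c (11.74 and 9.15). So were miR-342-5p (9.14 in syngeneic) and miR-501-3p (12.24 ± 4.20 in allogeneic). The calls of miR-501-3p (held under 10 of 21 alternatives) and of miR-201 in syngeneic hearts (9 of 21) were lost under most alternatives. The largest falls were those of miR-187 (at least 1524-fold lower in allogeneic hearts, log2 fold change -10.57 ± 0.30), miR-201 (at most -7.14 in allogeneic, -5.53 in syngeneic with 1 of 3 arrays detected), miR-137 (-5.66 and -5.80), miR-153 (-4.15, and at most -7.25 in syngeneic) and miR-384-5p (-4.28 in allogeneic). In syngeneic hearts miR-384-3p (at most -3.66) and miR-547 (-3.23) were also among them. Syngeneic hearts also held less miR-187 than normal hearts (-2.43 ± 0.30, 5.38-fold lower). Scaling to MammU6 left 58 allogeneic and 24 syngeneic calls, and a 2-fold change with an unadjusted p under 0.05 gave 83 for syngeneic hearts.

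Against PBMC, syngeneic GIL had 66 assays higher and 73 lower of 229, and allogeneic GIL had 47 and 76. miR-214, made in connective tissue, and the muscle microRNA miR-133a were higher in GIL than in blood cells. miR-214 was undetected in PBMC and at least 15.11 log2 units higher in syngeneic and 11.67 in allogeneic GIL. miR-133a was 188-fold (7.55 ± 0.59) and 598-fold (9.22 ± 0.58) higher. The leukocyte microRNA miR-142-3p was lower in both (-3.45 ± 0.49 and -1.85 ± 0.48), as was miR-150, a microRNA of resting lymphocytes (-2.97 and -2.46). miR-155 was higher in allogeneic GIL (2.59 ± 0.37, adjusted p = 0.00267) and stood at 0.62 ± 0.38 in syngeneic GIL without passing. Among the largest rises were also miR-379 (at least 14.15 in syngeneic and 11.61 in allogeneic GIL), miR-411 (12.87 and 10.89), miR-741 (at least 17.43 in syngeneic), miR-495 (at least 12.77 in syngeneic), and miR-133b and miR-204 (at least 14.11 and 11.53 in allogeneic). Undetected in a GIL group were miR-98 (at most -9.99 in syngeneic and -9.48 in allogeneic), miR-23a (-9.05 and -8.54), and, in syngeneic GIL, miR-425 (-13.95 ± 4.03) and miR-211 (-10.04). In allogeneic GIL these were miR-339-3p (-10.64 ± 2.70), its rat-named assay (-8.79) and miR-503 (-7.77). Over the GIL and PBMC arrays, the software had marked the 1 well with a Ct for miR-23a and 1 of 2 for miR-425. It had also marked 3 of 4 for miR-211 and 4 of 4 for miR-741. miR-669a (-8.27 ± 2.59) was detected on 1 of 3 syngeneic arrays. Scaling to snoRNA135 with snoRNA202 left 62 calls for allogeneic GIL, and the arrays of these 2 groups alone left 71.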

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

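Of the tests in this part, that of the difference between hearts and GIL was planned, and the tests of the Dlk1-Dio3 pattern and of other splits were chosen after the results were seen. Of the 96 named assays tested in both tissues, 41 had an allogeneic effect that differed between hearts on day 7 and GIL on day 5, by the limma interaction at an adjusted p from 7.44e-04 to 0.0455. Values below are the heart effect minus the GIL effect in log2 units, relative to the microRNA reference. Strain of the heart in hearts and run day in GIL differed with the group and were not separated from these effects. Under the 5 other scalings 11 of the 41 were called in all, and 40 kept their direction. miR-21 was -0.01 when scaled to MammU6, where miR-222 was 0.20, miR-221 0.50 and miR-183 0.85. The calls of miR-183, miR-221, miR-222, miR-376a, miR-379, miR-34b-3p and miR-125a-3p were lost under all 5.

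In the Dlk1-Dio3 cluster the difference was 2.69 for miR-410, 2.79 for miR-495, 5.90 for miR-409-3p, 6.59 for miR-382 and 2.25 for miR-127. It was 1.81 for miR-376a, 2.01 for miR-434-3p, 1.74 for miR-379 and 4.34 for miR-134. Each fell in GIL, and miR-434-3p was also called lower in hearts (-1.01). Muscle and miR-30 microRNAs differed the other way, miR-133a by -3.34, miR-133b by -3.33, miR-1 by -3.19, miR-30e by -1.64, miR-30c by -1.29, miR-30a by -1.24 and miR-30d by -1.23. Among those with the larger rise in hearts were miR-685 (5.23), miR-451 (3.32), miR-147 (3.19), miR-210 (2.398), miR-183 (1.79), miR-221 (1.43), miR-222 (1.13) and miR-21 (0.92). Lower in GIL were the rat-named miR-351 (4.17), miR-741 (12.001, with 4 of 4 of its GIL wells marked by the software), miR-125b-3p (at least 5.85), miR-503 (at least 4.53), miR-672 (at least 4.27), miR-31 (2.37), miR-132 (2.02), miR-125a-5p (1.60), miR-125a-3p (1.61) and miR-34b-3p (1.26). The remaining differences were -2.23 for miR-135a, -2.12 for miR-29c, -2.39 for miR-547, -0.97 for miR-181a, -1.28 for miR-203, -1.07 for miR-126-5p and -0.88 for miR-23b. Of the assays in this paragraph, miR-125a-3p, miR-30a, miR-30d, miR-181a, miR-203 and miR-23b were not called in either tissue alone.

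For the lower Dlk1-Dio3 microRNAs in allogeneic GIL, the tables argue against the late Ct values of allogeneic pool 3 as the whole cause, since the list median was -2.21 and 19 of 24 assays were lower without that pool. The number of calls depends on scaling, with 9 of 24 lower when scaled to MammU6 and 2 when scaled to snoRNA135 with snoRNA202, while the list median stayed at -1.92 and -2.08. They also argue against a low or high starting level, since 10000 random lists of assays matched in syngeneic level had a median of -0.06 (95% between -0.75 and 0.46, lowest -1.55) against -2.73. Fewer fibroblast-like cells carried over from the allogeneic grafts may account for part or all of the fall and stay open. The 3 miR-199a and miR-214 assays had a median of -1.38, a fall smaller than that of the list. They were spread, since miR-214 stood at -3.45, beyond the list median, and 3 of 6 miR-199a-5p wells with a Ct were marked by the software. In PBMC, 17 of the 24 Dlk1-Dio3 assays were undetected. Cardiac muscle assays had a median of 1.66, so less carry-over of all graft tissue alike is argued against. Run day cannot be told apart from group in GIL, as 0 run days held both, and a difference between the lymphocytes themselves was not tested apart from these.

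Of 100 splits drawn from the 200 joint regroupings of the heart and GIL arrays, 1 (the real grouping) gave as many interaction calls, 57. The highest other gave 49 with the GIL groups swapped and the heart arrays mixed. Much of the count can therefore come from the GIL effect. Regroupings that mix both tissues remove the allogeneic effect from each. The splits thus test for no effect in either tissue and cannot decide whether the effect differs between tissues. For the assays called the same way in both tissues the real grouping gave 24, 1 of 100 splits gave as many and the highest other gave 0. The other splits called so few assays within a tissue that at most 1 could have been shared, so this count does not test whether the overlap exceeds chance.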

How the results depend on the processing

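Scaling to snoRNA202 with undetermined wells at 40, the run day as a random or fixed block, the limit set after scaling and the removal of marked wells were chosen after the data were seen, and the other alternatives were planned. No called value of a named assay reversed, but miR-133a in hearts fell to a difference of 0 by quantiles. Over the alternatives run, 4089 values of named assays kept direction and side of the threshold, 477 lost the threshold (miR-133a at 0 among them), 93 gained it, and 935 list medians moved by less than their spread and 96 by more. In 17 pairs of an assay and a comparison, 54 values changed sign without being called in the main or the alternative setting. Scaling 2 cards together was not run, because each array is 1 card.

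The allogeneic against syngeneic heart count of 77 was 34 when scaled to MammU6 and 42 to 81 with each array left out. It was 77 with run day as a random block and 2 with run day as a fixed block, in which 6 arrays share 4 run days. The fixed block left 1 residual degree of freedom in place of 4, which ended the calls, while their median size went from 1.59 to 1.44 log2 units and their median SE from 0.29 to 0.26. With the replicate number as a block (a paired fit) it was 46, with correlations of -0.09, -0.13 and -0.05 between pools of the same number after removal of group means, so that the numbers give little sign of pairing. The GIL count of 73 was 31 when scaled to snoRNA135 with snoRNA202, 35 to snoRNA202 with undetermined wells at 40, and 40 to 73 with each array left out (61 of the 73 calls held without allogeneic pool 3).

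Against normal hearts, the syngeneic count of 46 was 24 when scaled to MammU6 and 83 with a 2-fold change and an unadjusted p under 0.05, and 31 to 55 with each array left out, and the allogeneic count (63 higher and 62 lower) was 58 when scaled to MammU6. Against PBMC, the allogeneic GIL count of 123 was 62 when scaled to snoRNA135 with snoRNA202, 62 to snoRNA202 with undetermined wells at 40, and 71 with the arrays of these groups alone.

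The interaction count of 57 was 15 (MammU6), 27 (snoRNA135 with snoRNA202), 29 (snoRNA202 with undetermined wells at 40) and 31 (replicate block). The count called in both tissues, 24, was 9, 12 and 14 under those scalings, 14 with no filter, 11 with the replicate block, 1 with run day as a fixed block in hearts alone, and 12 to 26 with each array left out. The number of lists called, 7, was 4 with run day as a fixed block in hearts alone, where the 5 heart lists became 2 and the 2 GIL lists stayed as they were, since no block could be fitted in GIL. Fewer arrays or degrees of freedom limit the left-out and blocked counts, and for the other settings the cause was not tested. Late Ct limits the falls in allogeneic GIL pool 3, whose reference Ct of 28.0 leaves the least range above the detection limit.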

Other observations

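All tests in this part, apart from the planned fits whose values are quoted, were chosen after the results were seen. MicroRNA genes that lie together in the genome changed alike. Over clusters of neighbouring genes (within 10 kb in GRCm38.p6), the mean difference in log2 fold change between members was 0.77 in hearts (23 clusters, 76 assays), against 1.47 for randomly assigned members, and 1.17 against 2.34 in GIL (18 clusters, 62 assays), both at a permutation p of 1e-04, the smallest that 10000 permutations can give. Without the Dlk1-Dio3 clusters the values were 0.78 against 1.69 in hearts (permutation p = 1e-04) and 1.16 against 1.60 in GIL (permutation p = 0.0089). This is consistent with shared primary transcripts, for which it was a test that could have failed (permutation p = 1e-04 in both tissues for all clusters, and up to 0.0089 in the other versions). The matching of names was widened and each cluster given equal weight after a first run, and with each pair weighted equally the permutation p was 1e-04 in hearts and 0.0066 in GIL. A gene was found for 98.2% of the 335 mouse-named assays, and the 288 with 1 gene were used. None was found for miR-685.

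Of the clusters so found, the 19 assays from miR-379 to miR-410 had 14 members lower in allogeneic GIL (camera adjusted p = 1.83e-04, adjusted p = 0.136 with an estimated correlation) and the 6 assays from miR-337 to miR-136 had 5 lower (0.010, adjusted p = 0.305 with an estimated correlation). In hearts, the stem cell cluster of miR-302b and miR-367 had 2 of 3 tested members lower, and the X-linked cluster of miR-500, miR-501 and miR-362 had 2 of 6 higher, and neither passed (adjusted p = 0.106 and 0.0676).

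For miR-187, which was not detected in allogeneic hearts, the tables argue against dilution by infiltrating cells, since a loss of graft tissue lowers its microRNAs alike, and the cardiac muscle list had a median of -1.67 (SD of its members 1.06) against -8.15 or lower for miR-187. The fall of miR-187 exceeded that of 6 of the 7 members by more than 2 combined SE, but not that of miR-490 (-4.12 ± 2.47). They also argue against run day as the whole cause, since within 2 of 2 run days with both groups it was undetected on allogeneic arrays alone (differences of -8.26 and -7.79). A BALB/c variant that the assay cannot read stays open, because its Ct of 25.04 in normal BALB/c hearts speaks against it but comes from 1 array. The strain of the heart differs with the group, and rejection and strain were not tested apart.

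The 41 microRNAs higher in allogeneic hearts could come from infiltrating cells. Scaled together over the assays detected on all 14 arrays, 2 of the 41 lay above every measured component (syngeneic and normal hearts, GIL and PBMC) at a limma adjusted p under 0.05, miR-685 by 2.15 ± 0.42 log2 units (0.00725) and miR-362-3p by 0.79 ± 0.27 (0.0456), which a mixture of the cells as measured would not give. A first version of this test, with each group's own error and a margin of 2 SE, put 6 above. In both versions the 41 had been chosen as high on the same allogeneic heart arrays, which favours a level above the components. Of the other 39, 24 had a higher mean level in GIL or PBMC than in allogeneic hearts, as a mixture needs, with no test required. For most of these the highest level was that of the lone PBMC array and not of GIL. miR-467b, for example, stood at 2.23 in PBMC, -3.49 in allogeneic GIL, -2.69 in syngeneic GIL and -0.10 in allogeneic hearts. Admixture stays open for both parts, since GIL were taken on day 5 and hearts on day 7.

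With 10 splits of 6 arrays, a share under 0.05 cannot be reached. The real heart grouping gave 77 calls (1 of 10 splits as many, highest other 2) and 5 lists (1 of 10, highest other 3), and the real GIL grouping gave 73 calls (1 of 10, highest other 0) and 2 lists (5 of 10 splits as many, highest other 4).

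Some wells had values far from the rest. miR-667 had a Ct of 12.8 and 12.5 in syngeneic GIL pools 1 and 2 and was undetermined in pool 3. miR-741 had a Ct of 17.9 to 28.5 in the 4 GIL wells with a value and 27.8 to 29.99 in the 7 heart wells.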
